A study of Mus musculus with 6 samples.

How the data were processed

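RNA from mouse liver tissue was sequenced in 6 libraries. Per the labels, 3 libraries came from mice without G3bp1 in hepatocytes only (HKO) and 3 from litter controls (Flox), and the mice were given high-fat food from 6 weeks of age for 12 weeks before the tissue was frozen. Total RNA was isolated on Qiagen RNeasy Plus columns and 1.3 µg per sample entered a NEBNext Ultra RNA library, per the labels' protocols. That kit does not mark strand, so reads of a gene and of an antisense neighbour could not be told apart. The labels give each library as a separate sample of its group and speak of mice. None of them states that each library came from its own animal, so p-values measure the spread between these samples, which may be technical. Where the text speaks of a liver, it means the sample of 1 library.

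The authors deposited 1 table of FPKM values (a unit that divides the reads of a gene by its length and by a library size). It holds 1 value per gene and library, so replicates were not pooled. The genome builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here. The deposited table also holds a gene length in bases for each gene, which was used to recover reads. It holds 54532 genes, of which 22046 are protein-coding, and 99.8% of its gene identifiers occur in GENCODE release M21, an annotation of the same build that was used for copies and overlaps. The symbols of 27 genes had been turned into calendar dates, and these genes were not matched to any list.

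Within a library, each FPKM value times the gene length was a whole multiple of 1 step. With that step taken as 1 read, 100% of the values above 0 in every library lay within 0.02 reads of a whole number. The recovered reads summed to 15804115 in Flox 1, 15893656 in Flox 2, 16331199 in Flox 3, 16810095 in HKO 1, 16499832 in HKO 2 and 17954066 in HKO 3. The library size behind the deposited FPKM was 0.934 to 1.055 times these sums, and it matched the sum times a median-ratio size factor in all 6 libraries, with a difference of 0%. The FPKM were therefore already scaled so that the typical gene was level between libraries. In a gene of 1 kb, 1 FPKM stood for 14.9 to 18.5 reads, so values near the filter described below rest on few reads. A gene with no reads could still have held up to 3 reads per library, the limit that a count of 0 allows for counting error only.

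Because FPKM are not counts, each comparison used log2(FPKM + 1) with a pseudocount of 1 in limma 3.58.1 under R 4.3.3 (trend over expression, robust moderation, statmod 1.5.0), two-sided. Genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested, which left 11856. P-values were adjusted with the Benjamini-Hochberg method and the threshold was 0.05. A fold change is given as HKO minus Flox on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Group values are means ± SD over 3 libraries. With 3 against 3 libraries an exact permutation test cannot give a two-sided p below 0.1.

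The comparison, the tests, the settings tried beside them (except 4 named below), the rule for naming genes and 46 lists of genes were fixed before the data were examined. The lists cover the mitochondrial calcium uniporter, oxidative phosphorylation (OXPHOS), fatty acid and cholesterol metabolism, other liver functions, stress and immune responses, and markers of the cell types a liver sample could hold. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, and its p-values were adjusted over the 41 lists tested. Camera with a correlation estimated from the residuals, and fry, were run beside it. A list score is the mean over members of the log2 value centred on each gene's mean over the 6 libraries. Members past the threshold were counted over all genes tested and adjusted over the list alone.

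The genes named in the text are G3bp1, G3bp2 and the uniporter genes Mcu, Mcub, Micu2 and Smdt1 in any case. They further include, in each direction, the 10 genes with the largest fold change among those that passed with HKO and Flox libraries not overlapping, leaving out predicted genes and pseudogenes. Where fewer than 10 passed, the number was filled up with the smallest unadjusted p among non-overlapping genes of at least 1 FPKM on average, given as genes that did not pass. Up to 4 members with the smallest p stand for each list that passed and up to 2 for the other lists described. The rule also covers 2 genes that are not reported here. Gm12411 falls outside this rule as a predicted gene, and was named after its values were seen because it was the gene that passed.

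The longest transcript of each of 144 genes that the rule could name was compared with all transcripts by blastn 2.17.0. A copy was a transcript of another gene with at least 97% identity over at least 80% of the length. Such copies were found for 8 of these genes (Gm12411, Mup13, Hba-a2, Rps3a1, Rps4x, Cyp2a4, mt-Nd3 and mt-Nd4l). Their values are uncertain because the authors' counting could have split reads between copies. Hba-a1 is the copy of Hba-a2, so its values are uncertain as well. Exons of 16 genes overlapped those of another gene by at least 5%, among them Afmid, Fdps, G3bp2, Csf1r, H2-DMa, Smdt1, Gadd45a and Acaa1b, which makes their values uncertain in the same way. In that release 134 of the 144 genes had the same start and end as in the deposited table. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

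The procedure was tested on simulated data drawn from the means and library sizes of these libraries, with 200 genes changed. Of 11921 simulated genes tested for HKO against Flox, the adjusted test called 10.8% of 65 genes changed 1.5-fold, 54.5% of 66 genes changed 2-fold and 93.7% of 63 genes changed 4-fold, and 7 of 11727 unchanged genes. Camera called the list that had been shifted by -0.25 and 0 other lists. Genes were drawn independently of each other, so members of a list did not correlate in this simulation. It therefore does not measure false calls of camera where members correlate, as they did at an estimated 0.53 among nuclear-encoded OXPHOS genes.

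The settings tried beside these were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, rescaling to TPM (values with the same sum in each library), median-ratio factors and quantile normalization. Further settings were limma without robust moderation, limma with array weights, the replicate number as a block, camera with an estimated correlation, fry, and each library left out. Limma's voom on the recovered reads, FPKM scaled by assigned reads, protein-coding genes only, and a term for HKO 2 and HKO 3 were added after the values were seen. That term leaves HKO 1 alone to be compared with the 3 Flox libraries. In it limma pools the spread of the other libraries, and the lone library is assumed to vary like them, so that its calls describe HKO 1 and not the HKO group. No gene of the table was left without a name, and all of its columns of values were assigned to samples.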

Results

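Liver RNA was profiled in mice whose hepatocytes lacked G3bp1 (HKO, 3 libraries) and in floxed litter controls (Flox, 3 libraries), all after 12 weeks on high-fat food. The labels do not state that each library came from its own animal. G3BP1 is an RNA-binding protein that nucleates stress granules. The study asked how it affects non-alcoholic steatohepatitis, the inflamed form of fatty liver, and named the mitochondrial calcium uniporter (MCU) complex in its title. The single comparison is HKO against Flox. Between 15804115 and 17954066 reads per library were assigned to genes. Libraries correlated with each other at r = 0.975 to 0.989 within a group and at 0.978 to 0.983 between groups (Pearson, across genes, which are not independent replicates). The first and second principal components held 33.6% and 23.8% of the variance. On the first, Flox 1, Flox 2 and HKO 1 lay at -14.9, -23.5 and -4. Flox 3, HKO 2 and HKO 3 lay at 14.1, 13.8 and 14.5 on it, so it did not separate the groups. Xist, which is transcribed in females, lay between 0 and 0.019 FPKM, and the Y-linked Ddx3y between 12.2 and 16.5 FPKM in the 6 libraries.

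G3bp1 (ENSMUSG00000018583, chromosome 11, 55469685 to 55504838 on the plus strand, GRCm38) was lower in every HKO library than in every Flox library. It stood at 8.46, 8.46 and 9.10 FPKM in the Flox livers (918, 887 and 1080 reads) and at 4.66, 4.28 and 4.44 FPKM in the HKO livers (584, 504 and 581 reads). The group means were 8.67 ± 0.37 and 4.46 ± 0.194 FPKM (SD, n = 3), a level 48.6% lower in HKO, and each library thus matched its label. Endothelial, immune and stellate cells of the liver keep the gene in this design, and which exons were deleted is not given in the sources used here. The log2 fold change was -0.83 (SE 0.088), with an adjusted p of 0.11 in limma over all genes tested and an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. With limma's voom on the recovered reads the adjusted p of G3bp1 was 0.037, and over the alternatives it ranged from 0.0275 to 0.838. Its paralog G3bp2 stood at 4.32 ± 1.66 FPKM in Flox and 4.38 ± 0.349 in HKO (log2 fold change 0.06, adjusted p = 0.943 in limma). Of 29 stress granule protein genes tested, 19 were higher and 10 lower, with a mean log2 fold change of 0.06, and the list did not pass (camera adjusted p = 0.0887). It passed, as higher in HKO, under 6 alternatives: at a mean FPKM of at least 5 (adjusted p = 0.00192), under TPM (0.035), under quantile normalization (0.0339), scaled by assigned reads (0.037), with array weights (0.0155) and without Flox 3 (0.0173). Its mean was 0.03 to 0.10 with 1 library left out and 0.23 under TPM. Within it Pabpc4, a poly(A)-binding protein, stood at 5.98 ± 0.12 FPKM in Flox and 8.11 ± 0.0527 in HKO. Atxn2 stood at 4.25 ± 0.289 and 3.13 ± 0.143 FPKM, and neither gene passed (adjusted p = 0.58 for both in limma).

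Genes of the mitochondrial calcium uniporter were slightly lower in HKO as a group. Of 13 tested members 12 were lower and 1 higher, with a mean log2 fold change of -0.16 ± 0.174 (SD over members), and the list passed (camera adjusted p = 0.00661). The adjusted p was 0.464 with an estimated correlation, and 0 members passed adjusted over the list alone. That estimate was 0, below the preset 0.01, and the unadjusted p of camera with it was 0.0319. The call was thus lost in that fit without a higher correlation. An estimate from 6 libraries is imprecise, so correlation between members is not excluded. Mcu, the pore subunit, stood at 3.84 ± 0.41 FPKM in Flox and 3.42 ± 0.227 in HKO (log2 fold change -0.13, adjusted p = 0.741 in limma). Micu2, which encodes a calcium-sensing regulator of the pore, stood at 14.3 ± 1.21 FPKM in Flox and 10.1 ± 1.02 in HKO, without overlap between the groups. It did not pass over all genes (log2 fold change -0.46, SE 0.112, adjusted p = 0.58 in limma). The lithium-permeable exchanger gene Slc8b1, which carries calcium out of the matrix, stood at 18.7 ± 4.06 and 12.1 ± 2.46 FPKM. Smdt1, which encodes the regulator EMRE, stood at 44.3 ± 5.64 and 43.3 ± 11.5 FPKM, and its exons overlap those of Pheta2 by 16.6%. Mcub lay below the filter, with 6, 2 and 0 reads in Flox and 5, 2 and 0 in HKO, too few to detect a difference. The group call ended under TPM (adjusted p = 0.107) and with genes of at least 5 FPKM on average (0.0622). Under TPM 10 of the 13 members were higher, and 2 relative to the median of all genes. Mcu, Smdt1 and Letm1 were among those higher in HKO under TPM, at log2 fold changes of 0.02, 0.12 and 0.01.

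Over all 11856 genes tested, 1 gene was lower and 0 were higher in HKO at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 904 genes, 365 higher and 539 lower, where chance would give 593. Limma's voom on the recovered reads called 0 genes higher and 3 lower, namely G3bp1, Gm12411 and Mup13. HKO libraries lay all above or all below Flox libraries in 13.3% of the genes tested (718 above and 855 below), where chance gives 10%. The gene that fell in HKO was Gm12411 (ENSMUSG00000081559, chromosome 4, 45550017 to 45550499 on the plus strand, GRCm38), a processed pseudogene of the ribosomal protein gene Rpl21. It lies outside the rule for naming genes and was chosen after its values were seen. It stood at 19.97 ± 2.89 FPKM in Flox and 4.64 ± 0.583 in HKO (146, 165 and 140 against 35, 37 and 47 reads). Limma gave a log2 fold change of -1.89 (SE 0.135) and an adjusted p of 0.0211. Its transcript is up to 99.17% identical to 29 copies elsewhere in the genome, so its reads are uncertain. The call ended with no filter and with the replicate block, both at a log2 fold change of -1.89. It also ended without Flox 1, without Flox 2, without HKO 2 and without HKO 3, at -1.97 to -1.79, where 0 genes passed. Without HKO 1 the counts were 12 lower and 1 higher. Among these was mt-Tp, the mitochondrial proline tRNA, likewise chosen after its values were seen. It stood at 1280, 1380 and 1240 FPKM in the Flox livers and 1380, 377 and 406 in HKO 1, HKO 2 and HKO 3.

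Other genes with the smallest p-values did not pass over all genes, and their values are given as such. Among those lower in HKO, Mup13, a major urinary protein made by hepatocytes, stood at 60.8 ± 5.59 FPKM in Flox and 24.5 ± 2.26 in HKO (adjusted p = 0.0734 in limma). It has 3 copies of up to 99.01% identity and is uncertain. Afmid, a kynurenine pathway enzyme whose exons overlap those of Gm20708 by 44.2%, stood at 9.88 ± 1.33 and 5.26 ± 0.512 FPKM. The glycolysis regulator Pfkfb1 stood at 8.54 ± 1.31 and 4.47 ± 0.775 FPKM and the kinase gene Dyrk1b at 8.11 ± 1.06 and 4.44 ± 0.391. The tumour suppressor gene Trp53 stood at 5.04 ± 0.253 and 3.25 ± 0.301 FPKM. Pnldc1 stood at 2.35 ± 0.514 and 0.874 ± 0.29 FPKM and the keratin gene Krt23 at 1.62 ± 0.501 and 0.496 ± 0.152. Among those higher in HKO were several genes of myeloid cells. Clec4a3, a C-type lectin, stood at 1.07 ± 0.0797 FPKM in Flox and 2.09 ± 0.131 in HKO. Igsf6 stood at 0.927 ± 0.277 and 1.92 ± 0.148 FPKM, and the Fc receptor gene Fcgr3 at 3.08 ± 0.494 and 5.15 ± 0.731. Further genes were Plxnb1 (4.79 ± 0.486 and 7.18 ± 0.652 FPKM), Atp11a (2.27 ± 0.101 and 3.35 ± 0.134), Lbh (2.19 ± 0.0982 and 3.29 ± 0.305) and Zfp869 (4.96 ± 0.22 and 6.78 ± 0.233). The smallest adjusted p among genes higher in HKO was 0.455 in limma.

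**Figure D1:**
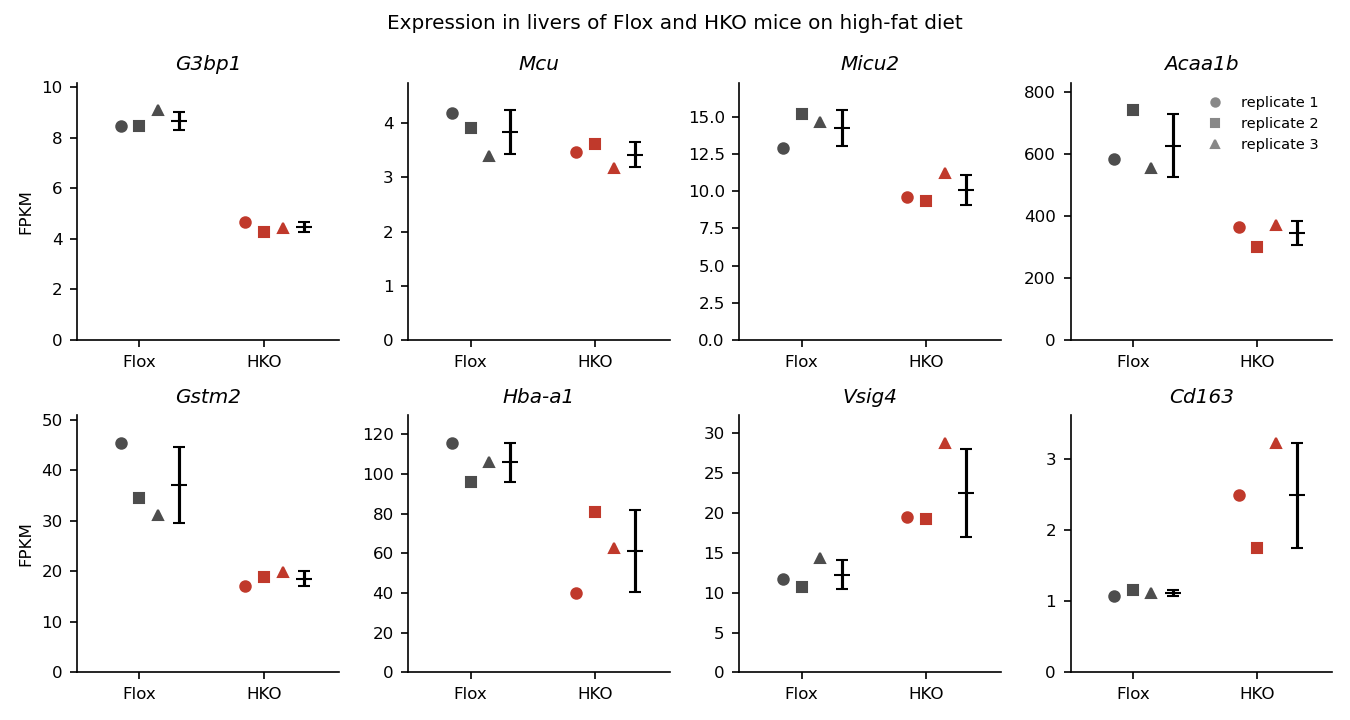
FPKM of 8 genes (y axes, starting at 0) in the livers of Flox and HKO mice (x axes), with 1 point per library, its shape giving the replicate number, and a bar for the mean ± SD of 3 libraries. G3bp1 lies between 8.46 and 9.10 FPKM in Flox and between 4.28 and 4.66 in HKO. None of these 8 genes passed the adjusted threshold over all genes. Under TPM Mcu was higher in HKO with a log2 fold change of 0.02. The values of Hba-a1 are uncertain because Hba-a2 is nearly identical to it.

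Genes of mitochondrial respiration were lower in HKO as a group. All 75 tested nuclear-encoded OXPHOS genes, which encode respiratory chain and ATP synthase subunits, had a lower mean in HKO, against 48 of the 75 under TPM (72 relative to the median of all genes) and 62 under quantile normalization. The mean log2 fold change was -0.24 ± 0.141 (SD over members), or 15.1% lower, and the list passed (camera adjusted p = 7.3e-11, adjusted p = 0.59 with an estimated correlation). The mean was -0.06 under TPM, -0.12 under quantile normalization and -0.16 scaled by assigned reads. Examples are Ndufs4, a complex I subunit, at 23.6 ± 1.92 FPKM in Flox and 18.2 ± 1.64 in HKO, and Sdhb, a complex II subunit, at 121 ± 15.8 and 92.3 ± 7.13. The complex I subunit genes Ndufs5 and Ndufs8 stood at 88.4 ± 11.3 and 64.3 ± 7.81 FPKM and at 96.4 ± 6.97 and 76.7 ± 3.16. At an unadjusted p under 0.05 there were 10 members, and 0 passed adjusted over the list alone. HKO 1, with a list score of 0.06, lay within the range of the Flox livers (-0.11 to 0.27). HKO 2 and HKO 3 lay at -0.23 and -0.18. Flox 1 and Flox 2 lay above HKO 1, at 0.20 and 0.27, and Flox 3 below it, at -0.11. A fit with a term for HKO 2 and HKO 3 compares HKO 1 alone with Flox, the lone library being assumed to vary like the others, and in it the list did not pass (adjusted p = 0.0547). The 13 mitochondrially encoded OXPHOS genes had a mean log2 fold change of -0.28 and did not pass (camera adjusted p = 0.0897). They passed, as lower in HKO, under TPM (adjusted p = 0.0464, with a mean of -0.11 and 8 of 13 lower), with array weights (0.0247), with the replicate block (0.0432), without Flox 3 (1.0e-04) and without HKO 2 (0.0477), and for HKO 1 alone against Flox (0.013). Their mean was -0.16 without Flox 1, -0.10 without Flox 2 and -0.59 without Flox 3, and under quantile normalization -0.12 with 7 of 13 lower. Among them mt-Nd3 stood at 107 ± 36.3 and 64.9 ± 20.2 FPKM and is uncertain because of a copy of 99.71% identity.

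Fatty acid oxidation genes were also lower in HKO. All 22 tested genes of mitochondrial beta-oxidation and ketogenesis had a lower mean, and 15 of them under TPM (mean log2 fold change -0.24, camera adjusted p = 1.8e-06, adjusted p = 0.54 with an estimated correlation). Among these enzymes were Eci1 (165 ± 25.4 FPKM in Flox and 120 ± 19.5 in HKO), Decr1 (56.5 ± 5.53 and 44.4 ± 6.17) and Hadh (79.7 ± 8.76 and 64.2 ± 7.86). Of 21 peroxisomal and microsomal fatty acid oxidation genes 20 were lower (mean -0.35, camera adjusted p = 1.8e-05, with an estimated correlation 0.464). Of 23 targets of the fatty acid receptor PPARalpha 21 were lower (mean -0.41, camera adjusted p = 1.7e-06, with an estimated correlation 0.464). Acaa1b, a peroxisomal thiolase in both of these lists, stood at 626 ± 101 FPKM in Flox and 345 ± 38.2 in HKO. It was the 1 member of each that passed adjusted over the list alone (adjusted p = 0.58 over all genes in limma). Plin2, a coat protein of lipid droplets, stood at 186 ± 38.7 FPKM in Flox and 122 ± 8.1 in HKO. Under TPM the means of the 3 lists were -0.07, -0.20 and -0.28, and under quantile normalization -0.11, -0.27 and -0.34. HKO 1 lay at list scores of 0.02, 0.21 and 0.10, within the ranges of the Flox livers. The mitochondrial and peroxisomal lists did not pass for HKO 1 alone against Flox (adjusted p = 0.0781 and 0.186). The mean of the mitochondrial list was -0.16 without Flox 2, and that of the peroxisomal list was -0.15 without HKO 3 and -0.54 without HKO 1.

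Lipid transport and sterol genes moved in opposite directions. Of 26 genes of fatty acid uptake and lipoprotein export 19 were lower in HKO (mean log2 fold change -0.16, camera adjusted p = 0.0421, adjusted p = 0.54 with an estimated correlation), with a mean of 0.02 under TPM. The fatty acid-binding protein genes Fabp2 and Fabp1 stood at 152 ± 1.31 FPKM in Flox and 98.8 ± 14.7 in HKO, and at 5564 ± 962 and 3974 ± 391. Apoc3, an inhibitor of lipoprotein clearance, stood at 2322 ± 442 and 1729 ± 172 FPKM. Of 25 cholesterol synthesis genes 21 were higher (mean 0.21, camera adjusted p = 0.0265, adjusted p = 0.785 with an estimated correlation). Sqle, squalene epoxidase, stood at 8.69 ± 4.08 and 15.9 ± 5.66 FPKM and Cyp51, a demethylase of lanosterol, at 30.1 ± 9.03 and 43.9 ± 17.3. In neither list did a member pass adjusted over the list alone (0 of 26 and 0 of 25). The first call ended without Flox 1, Flox 3 or HKO 2 (adjusted p = 0.096, 0.12 and 0.308), with means of -0.15, -0.18 and -0.09. The sterol call ended without Flox 1, Flox 2, HKO 2 or HKO 3 (adjusted p = 0.385, 0.116, 0.987 and 0.0714), with means of 0.08, 0.16, 0.02 and 0.19. Its mean was 0.39 without Flox 3 and 0.42 without HKO 1. For HKO 1 alone against Flox the first list did not pass (0.687) and the sterol list was lower in that 1 library (adjusted p = 0.00858). De novo lipogenesis genes did not pass (18 tested, mean -0.11, camera adjusted p = 0.515). Their mean was 0.24 without Flox 3, 0.23 without HKO 1 and -0.58 without HKO 3, where they passed as lower (adjusted p = 2.7e-05), as they did for HKO 1 alone against Flox (1.7e-04). Their scores were high in Flox 3 and HKO 3 (0.76 and 0.88) and between -0.73 and -0.23 in the other 4 livers. Triglyceride synthesis and lipid droplet genes did not pass either (23 tested, mean -0.15, camera adjusted p = 0.0686). They passed, as lower in HKO relative to other genes, with no filter (adjusted p = 0.0382), under TPM (0.0451, with a mean of 0.00), without Flox 1 (0.00912) and without HKO 3 (0.0157). Their mean was -0.06 without Flox 2 and -0.08 without HKO 2. G0s2, an inhibitor of triglyceride breakdown, stood at 323 ± 12.5 and 203 ± 67.2 FPKM.

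Markers of liver macrophages were higher in HKO. All 15 tested Kupffer cell markers, genes of the resident macrophages of the liver, had a higher mean in HKO, also under TPM, quantile normalization and scaling by assigned reads. The mean log2 fold change was 0.54 ± 0.288 (SD over members), and the list passed (camera adjusted p = 3.8e-07, adjusted p = 0.464 with an estimated correlation). The complement receptor gene Vsig4 stood at 12.2 ± 1.83 FPKM in Flox and 22.5 ± 5.47 in HKO, and the haemoglobin scavenger receptor gene Cd163 at 1.11 ± 0.0435 and 2.49 ± 0.743. The growth factor receptor gene Csf1r stood at 6.60 ± 1.38 and 11.5 ± 2.59 FPKM, and Adgre1, which encodes F4/80, at 2.52 ± 1.39 and 5.26 ± 0.713. These 4 markers passed adjusted over the list alone, while over all genes their adjusted p was 0.58 to 0.632 in limma. The exons of Csf1r overlap those of Hmgxb3 on the other strand by 15.1%. Of 10 tested markers of monocyte-derived and lipid-associated macrophages 9 were higher (mean 0.31, camera adjusted p = 7.1e-04, with an estimated correlation 0.464). Cd9 stood at 4.996 ± 0.7 and 7.19 ± 0.774 FPKM, Clec7a at 1.54 ± 0.25 and 2.77 ± 0.775 and Lyz2, lysozyme, at 39.0 ± 5.56 and 52.1 ± 8.36. All 8 tested B and plasma cell markers were higher (mean 0.25, camera adjusted p = 0.00372, with an estimated correlation 0.477), with the antigen receptor gene Cd79b at 0.504 ± 0.0444 and 0.874 ± 0.086 FPKM. In each of the last 2 lists 0 members passed adjusted over the list alone. Flox 3 lay above HKO 2 in the Kupffer score (0.14 against -0.02). The B cell list did not pass for HKO 1 alone against Flox (adjusted p = 0.303) and had a mean of 0.16 without HKO 2.

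Inflammatory and plasma protein genes were higher in HKO by small amounts. Of 24 acute-phase genes, which the liver induces in inflammation, 20 were higher (mean log2 fold change 0.23, camera adjusted p = 0.00119, adjusted p = 0.64 with an estimated correlation). Itih4, an inhibitor chain, stood at 502 ± 6.93 FPKM in Flox and 720 ± 197 in HKO and Apcs, serum amyloid P, at 85.9 ± 11.2 and 135 ± 50.3. A list of inflammatory cytokines and chemokines also held other inflammatory genes such as Casp1 and Icam1, and is called cytokines below. Of its 19 tested genes 14 were higher (mean 0.13, camera adjusted p = 0.00995, with an estimated correlation 0.59). Ccl24, an eosinophil attractant, passed adjusted over the list alone, at 1.04 ± 0.172 and 2.07 ± 0.185 FPKM (adjusted p = 0.58 over all genes in limma). Of 15 antigen presentation genes 10 were higher (mean 0.21, camera adjusted p = 0.00995, with an estimated correlation 0.777), with Cd74, the class II invariant chain, at 57.3 ± 7.58 and 91.1 ± 27.1 FPKM. Of 31 coagulation and complement genes 25 were higher (mean 0.10, camera adjusted p = 0.00409, with an estimated correlation 0.54). The complement gene C8a stood at 172 ± 29.9 and 248 ± 41.5 FPKM, and Hc, which encodes complement C5, at 131 ± 8.91 and 159 ± 6.82. In the acute-phase, antigen presentation and coagulation lists 0 members passed adjusted over the list alone. HKO 1 stood apart with scores of 0.65 for acute-phase and 0.57 for antigen presentation genes, and without it these means were -0.03 and -0.02 (adjusted p = 0.418 and 0.492). The acute-phase and coagulation calls ended without Flox 3 (adjusted p = 0.257 and 0.162), at means of -0.03 and 0.06. The cytokine and antigen presentation calls ended without Flox 1 (adjusted p = 0.067 and 0.0553) and without Flox 2 (0.143 and 0.0512), at a mean of 0.05 for cytokines in both cases. Further means over 1.5 times apart from the full ones were 0.43 (without Flox 1 or HKO 2) for acute-phase genes, 0.28 (without Flox 3) and 0.08 (without HKO 1) for cytokines, and 0.32 (without Flox 3) and 0.36 (without HKO 2) for antigen presentation.

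Interferon-stimulated genes were lower in HKO as a group, and they were high in 1 control liver, Flox 3. All 31 tested genes had a lower mean in HKO (mean log2 fold change -0.68, camera adjusted p = 3.0e-04, adjusted p = 0.779 with an estimated correlation), and 0 passed adjusted over the list alone. Isg15, an antiviral ubiquitin-like protein, stood at 16.4, 24.6 and 199 FPKM in Flox 1, Flox 2 and Flox 3 and at 27.6, 14.9 and 11.6 in the HKO livers. The list score of Flox 3 was 1.86, and that of the other 5 livers lay between -0.65 and 0.04. Without Flox 3 the mean was 0.08 and the call ended (adjusted p = 0.204), and without Flox 1 or Flox 2 the mean was -1.08 or -1.04. In HKO 1 alone against Flox the list did not pass (adjusted p = 0.324).

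Antioxidant genes were lower in HKO. Of 20 tested targets of the stress-response factor NRF2, 17 were lower (mean log2 fold change -0.29 ± 0.287, SD over members, camera adjusted p = 8.5e-05, adjusted p = 0.464 with an estimated correlation), and 3 passed adjusted over the list alone. Under TPM 13 were lower with a mean of -0.14, and under quantile normalization the mean was -0.20. These 3 were the glutathione transferase genes Gstm2 (37.1 ± 7.5 FPKM in Flox and 18.6 ± 1.43 in HKO) and Gsta4 (37.2 ± 5.19 and 24.9 ± 2.41) and the quinone reductase gene Nqo1 (4.81 ± 0.665 and 2.96 ± 0.507). Over all genes their adjusted p was 0.465 to 0.58 in limma. Of 12 cell cycle genes 9 were lower (mean -0.15, camera adjusted p = 0.00977, with an estimated correlation 0.464). The mean was -0.30 with voom on the recovered reads. Tk1, thymidine kinase, stood at 4.14 ± 0.451 and 2.80 ± 0.67 FPKM and Mcm2, part of the replicative helicase, at 0.667 ± 0.0164 and 0.390 ± 0.091. Of 20 pericentral hepatocyte genes, expressed next to the central vein, 16 were lower (mean -0.12, camera adjusted p = 0.0107, with an estimated correlation 0.464), with a mean of 0.06 under TPM. Aldh3a2, a fatty aldehyde dehydrogenase, stood at 92.2 ± 12.4 and 59.5 ± 7.71 FPKM. Of the cell cycle and pericentral genes 0 passed adjusted over the list alone. The cell cycle call ended without Flox 3 (adjusted p = 0.11), and the pericentral call without Flox 1 (0.067), and neither list passed for HKO 1 alone against Flox (0.0678 and 0.108).

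Red blood cell transcripts were lower in HKO. All 5 tested erythroid markers had a lower mean (mean log2 fold change -0.64 ± 0.245, SD over members, camera adjusted p = 3.2e-04, adjusted p = 0.464 with an estimated correlation), and 3 passed adjusted over the list alone. The globin gene Hba-a1 stood at 106 ± 9.96 FPKM in Flox and 61.2 ± 20.5 in HKO and Hbb-bt at 11.02 ± 2.29 and 6.28 ± 1.35. Hba-a2 (13.99 ± 3.39 and 8.27 ± 1.32 FPKM) has a copy of 99.81% identity, which is Hba-a1, so the values of both are uncertain. The list score was 0.25 to 0.39 in the Flox livers, and -0.73, 0.02 and -0.25 in HKO 1, HKO 2 and HKO 3. Ribosomal protein genes were higher in HKO by a small amount (57 of 76 higher, mean 0.06, camera adjusted p = 0.00372, adjusted p = 0.785 with an estimated correlation). Of these 0 passed adjusted over the list alone, and Rpl3 stood at 69.1 ± 1.3 and 84.5 ± 7.82 FPKM. The score of HKO 1 was 0.35 and that of HKO 3 was -0.23. The ribosomal call ended without HKO 1 (mean -0.10, adjusted p = 0.202) and without Flox 3 (mean -0.03, adjusted p = 0.646). Without each of the other libraries the mean lay between 0.09 and 0.19.

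The remaining lists did not pass with all libraries in the main fit. Hepatocyte markers had a mean log2 fold change of -0.10 (camera adjusted p = 0.37) and of -0.14 to -0.06 with 1 library left out, with Hpd, a tyrosine-degrading enzyme, at 1073 ± 124 FPKM in Flox and 710 ± 34.8 in HKO. Liver endothelial (0.10, adjusted p = 0.144), stellate and fibroblast (-0.02, 0.64), cholangiocyte (0.03, 0.64) and T and NK cell markers (0.22, 0.0564) did not pass camera. The last passed with no filter (adjusted p = 0.0317), with the replicate block (0.0268), without Flox 1 (0.00776) and without Flox 3 (0.0494). The mean of T and NK cell markers was 0.09 without Flox 2, 0.42 under TPM and 0.56 with voom on the recovered reads. Endothelial markers passed as higher without HKO 1 (mean 0.22, adjusted p = 0.00563) and without Flox 3 (0.19, 0.032), and had a mean of -0.01 without Flox 2. With 1 library left out the means lay between -0.11 and 0.07 for stellate and between -0.01 and 0.10 for cholangiocyte markers. Extracellular matrix and fibrosis genes did not pass either (0.00, adjusted p = 0.64), and Tgfb1, a driver of matrix deposition, stood at 1.53 ± 0.307 and 2.13 ± 0.336 FPKM. For stellate markers the mean was below 0 while the median (0.01) and the camera direction were above it. The unfolded protein and integrated stress response genes had a mean of -0.05 and a median of 0.00 (camera adjusted p = 0.892). The mean was 0.18 without Flox 2, where the list passed as higher (adjusted p = 0.0181), and -0.24 without Flox 3. The stress factor gene Atf3 stood at 2.63 ± 0.828 and 1.37 ± 0.355 FPKM. Mitochondrial unfolded protein response genes had a mean of -0.06 (adjusted p = 0.326). Apoptosis and p53 target genes had a mean of -0.08 (0.64), which lay between -0.13 and -0.03 with 1 library left out, with Gadd45a at 4.96 ± 0.661 and 3.17 ± 0.646 FPKM. Camera adjusted p-values were 0.362 for bile acid genes, 0.64 for gluconeogenesis and glycogen, 0.258 for periportal genes, 0.64 for CAR/PXR targets and 0.373 for immediate-early genes, at means of -0.03, -0.05, -0.11, -0.04 and -0.13. With 1 library left out these means lay between -0.09 and 0.04, -0.20 and 0.08, -0.19 and -0.03, -0.22 and 0.08, and -0.35 and 0.00. Bile acid genes passed under none of these 6 fits. Passing as lower were gluconeogenesis (adjusted p = 0.0103) and periportal genes (0.00974) without HKO 3, CAR/PXR targets without Flox 2 (0.0181) and immediate-early genes without HKO 2 (0.0148). Matrix genes were likewise lower without HKO 3 (0.0325). For matrix genes they lay between -0.14 and 0.10, and for clock genes between -0.10 and 0.04. Male-biased and female-biased liver genes had means of -0.17 (0.497) and -0.16 (0.988). The male-biased mean was 0.13 without Flox 2, 0.18 without HKO 1, -0.41 without Flox 3 (where the list passed as lower, adjusted p = 0.0494) and -0.43 without HKO 2 (likewise, 0.00757). The female-biased mean lay between -0.43 and 0.11 with 1 library left out. Circadian clock genes had a mean of -0.05 and a median of 0.00 (0.958), with the clock repressor gene Nfil3 at 10.4 ± 1.68 and 16.2 ± 3 FPKM. The 5 lists with fewer than 5 tested members were not tested. Of these, neutrophil, dendritic, adipocyte, mesothelial and digestive tract markers had means of -0.20, -0.15, -0.40, 0.36 and -0.35. With 1 library left out these lay between -0.43 and 0.10, -0.27 and -0.04, -0.66 and -0.10, -0.05 and 0.69, and -0.44 and -0.24. In the last, Fabp2 passed adjusted over the list alone.

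In all, 20 of the 41 lists tested passed camera with the preset correlation, 9 of them higher and 11 lower in HKO. The 6 libraries can also be split 3 against 3 in ways that mix genotypes. Those splits gave 10 to 20 lists by the same test, so the count alone does not mark an effect of genotype. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.464, and by fry for a shift in 1 direction 0 passed. Fry for changes in either direction gave 1 list, the uniporter genes (mixed adjusted p = 0.0387). Calls under scalings other than the deposited one split differently. Of the genes at an unadjusted p under 0.05, 40.4% were higher in HKO with the deposited scaling, 53.6% with quantile normalization, 66.7% with scaling by assigned reads and 89.4% under TPM. Among genes of at least 5 FPKM on average it was 26.4%. TPM shifted the median of all genes by 0.15 on the log2 scale. List means under TPM were 0.39 for cholesterol synthesis, 0.41 for acute-phase genes, 0.30 for cytokines, 0.39 for antigen presentation, 0.28 for coagulation and complement, -0.07 for cell cycle genes and 0.23 for ribosomal proteins. They were 0.76, 0.51 and 0.46 for Kupffer, other macrophage and B cell markers. Under quantile normalization they were -0.05 for lipid uptake and export, 0.23 for coagulation and complement, -0.02 for pericentral genes and 0.18 for ribosomal proteins. The FPKM of a library summed to 431497 to 494433 in Flox and to 412344 to 422735 in HKO. A part of that sum was Gm23935, a short RNA gene chosen after its values were seen, at 36099, 8471 and 28154 FPKM in Flox and 6701, 7015 and 9260 in HKO.

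**Figure D2:**
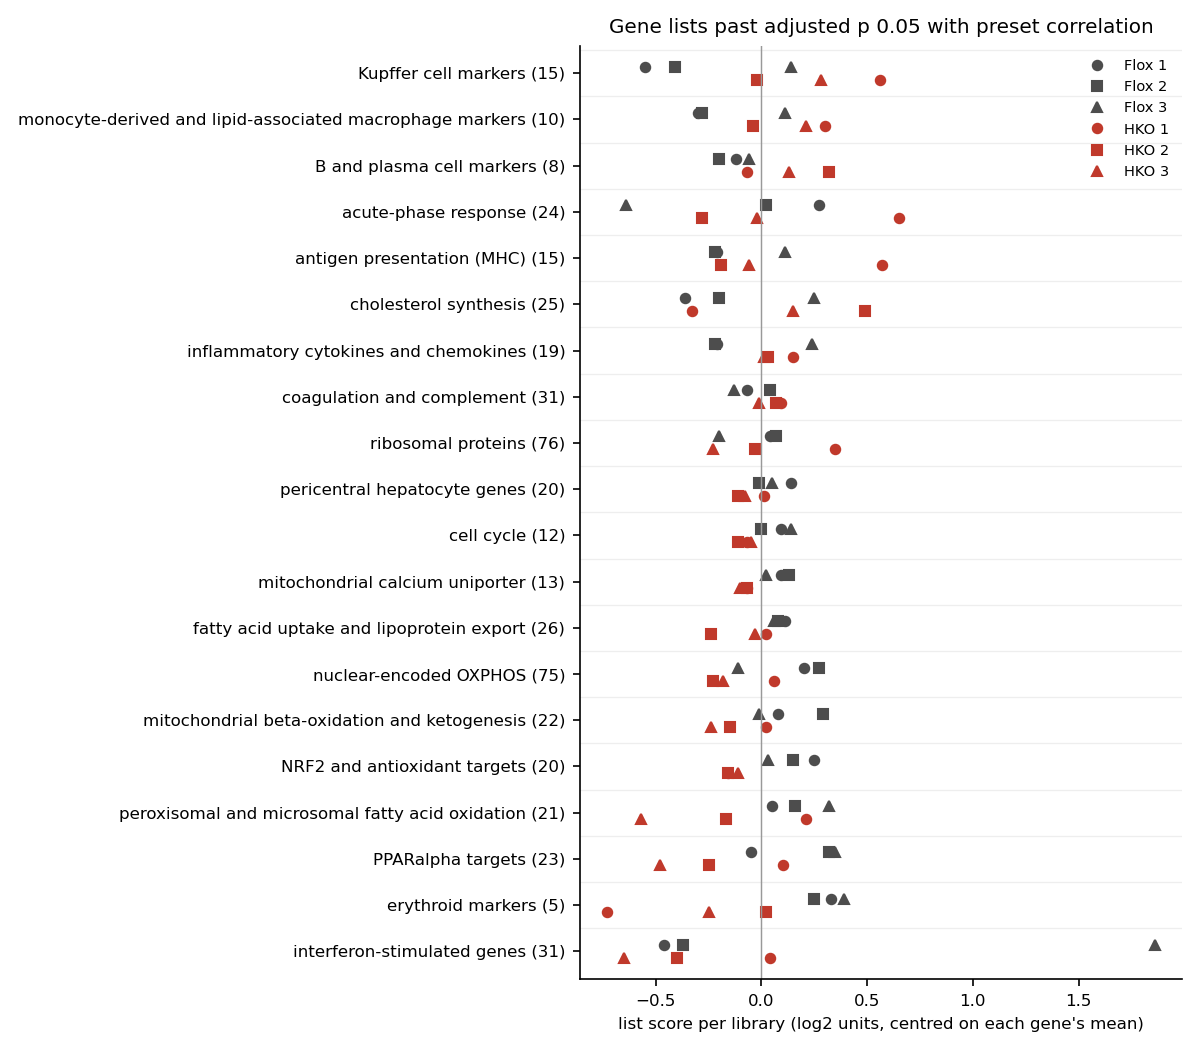
List score of each library (x axis, log2 units, centred on the mean of each gene) for the 20 gene lists that passed with a preset correlation (y axis, tested members in parentheses). Grey points are Flox and red points HKO, and the shape gives the replicate number. Kupffer scores run from -0.55 to 0.14 in Flox and from -0.02 to 0.56 in HKO. Flox 3 lies at 1.86 for interferon-stimulated genes, and under TPM the sign of the mean difference turned for the uptake and export list and the pericentral list and the mean of the uniporter list was 0.00.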

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

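Limma's voom on the recovered reads, FPKM scaled by assigned reads, protein-coding genes only and the term for HKO 2 and HKO 3 were alternatives chosen after the values were seen; the other alternatives were planned. The term leaves HKO 1 alone against the 3 Flox libraries, with the lone library assumed to vary like the others, so its values describe HKO 1 only. A planned edgeR fit was not run because the deposited values are FPKM. Over 19 alternatives 109 of 114 named genes kept the sign of their fold change and 5 turned under at least 1. With no filter, at a mean FPKM of at least 5 and with protein-coding genes only, each fold change equals that of the main fit. The same holds without robust moderation and with the replicate block. A gene named because its groups did not overlap cannot turn when 1 library is left out. These cases were fixed in advance and do not speak for the stability of the signs. G3bp1 stayed lower, at log2 fold changes of -0.96 to -0.73 and adjusted p-values of 0.0275 to 0.838. Of the lists that passed, PPARalpha targets, NRF2 targets, Kupffer markers, macrophage markers and erythroid markers kept their call under every alternative of fit, scaling and left-out library, and lost it with an estimated correlation and with fry. Over all lists and settings, a list kept direction and side of the threshold in 683 cases, lost the call in 80, gained one in 37 and turned in 54. With 3 libraries per group and 1 FPKM of a 1 kb gene standing for 14.9 to 18.5 reads, the simulation called 10.8% of 1.5-fold changes, so differences of that size were mostly not detectable. Replicate numbers were not used to pair the libraries, since deviations of same-numbered libraries correlated at 0.021, 0.015 and 0.07, although 2 of 3 Flox livers were closest to the HKO liver of their own number, so a pairing stays open. With the replicate block 0 genes were lower, 0 higher and 22 lists passed.

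The cause of the following differences was not tested except where fewer genes or libraries entered. Genes lower in HKO numbered 1 in the deposited scaling, 0 with no filter, 0 with protein-coding genes only (which leaves out Gm12411) and 0 for HKO 1 alone. They numbered 2 at a mean FPKM of at least 5, 3 with array weights and 3 with voom. Genes at an unadjusted p under 0.05 numbered 904, against 432 at a mean FPKM of at least 5, 2856 with array weights and 1389 under TPM. With an estimated correlation and with fry for a shift in 1 direction 0 lists passed. Log2 fold changes that turned were 0.016 for Mcu, 0.12 for Smdt1 and 0.011 for Letm1 under TPM, and for Smdt1 0.06 under quantile normalization and 0.021 scaled by assigned reads. For HKO 1 alone, with the term for HKO 2 and HKO 3, they were -0.054 for G3bp2, 0.345 for Smdt1 and -0.016 for Fdps. That of G3bp1 was -0.82 with array weights and -0.96 with voom, where it passed.

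Lists whose direction turned had these camera adjusted p-values. With no filter, cholangiocyte markers had 0.883. At a mean FPKM of at least 5, stress response genes had 0.371, CAR/PXR targets 0.839 and clock genes 0.967. With array weights, lipogenesis had 0.261, gluconeogenesis 0.742, apoptosis and p53 targets 0.915, male-biased genes 0.81, clock genes 0.603, ribosomal proteins 0.616 and cholangiocyte markers 0.963. With the term for HKO 2 and HKO 3 (HKO 1 alone), cholesterol synthesis had 0.00858, stress response genes 0.578, matrix genes 0.0211, female-biased genes 0.435, endothelial markers 0.111, stellate markers 0.111 and cholangiocyte markers 0.583. Under TPM, matrix genes had 0.77 and stellate markers 0.895. Under quantile normalization, bile acid genes had 0.931, gluconeogenesis 0.867, stress response genes 0.671, periportal genes 0.931, CAR/PXR targets 0.931 and hepatocyte markers 0.548. With a pseudocount of 0.1, female-biased genes had 0.949. Further calls lost without a turn were cytokines (0.137) and antigen presentation (0.0704) under TPM, cytokines (0.368) and pericentral genes (0.0652) at a mean FPKM of at least 5, and acute-phase genes (0.47), interferon-stimulated genes (0.408) and antigen presentation (0.0531) with array weights. Lipid uptake and export was lost under quantile normalization (0.506) and with a pseudocount of 0.1 (0.0662), pericentral genes under quantile normalization (0.157), and cholesterol synthesis with no filter (0.0786), under TPM (0.17) and scaled by assigned reads (0.0595). The uniporter call was lost under TPM (0.107) and at a mean FPKM of at least 5 (0.0622). Of the lists that passed with all libraries, those that kept direction but not the call for HKO 1 alone were nuclear-encoded OXPHOS (0.0547), beta-oxidation (0.0781), peroxisomal oxidation (0.186), lipid uptake and export (0.687), interferon-stimulated genes (0.324), cell cycle (0.0678), pericentral genes (0.108) and B and plasma cell markers (0.303). Calls gained were those of mitochondrially encoded OXPHOS under TPM (0.0464), with array weights (0.0247), with the replicate block (0.0432) and for HKO 1 alone (0.013). Stress granule proteins gained one at a mean FPKM of at least 5 (0.00192), under TPM (0.035), under quantile normalization (0.0339), with array weights (0.0155) and scaled by assigned reads (0.037). So did triglyceride and lipid droplet genes with no filter (0.0382) and under TPM (0.0451), T and NK cell markers with no filter (0.0317) and with the replicate block (0.0268), and male-biased genes (0.0393) and immediate-early genes (0.0427) under TPM. Passing for HKO 1 alone were lipogenesis (1.7e-04), bile acid genes (0.00308), gluconeogenesis (0.0211), periportal genes (0.0058), male-biased genes (6.7e-07) and immediate-early genes (0.0413).

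With each library left out in turn, 16 of the 37 gained calls arose, and genes higher in HKO numbered 0 to 1 and genes lower 0 to 12, both highest without HKO 1. Genes at an unadjusted p under 0.05 numbered 447 without Flox 1, 492 without Flox 2, 529 without HKO 2 and 1812 without Flox 3. Log2 fold changes ranged from -0.073 to 0.299 for G3bp2 and from -0.257 to 0.085 for Smdt1. Camera adjusted p-values ranged from 2.7e-05 to 0.987 for lipogenesis, 7.6e-06 to 0.987 for cholesterol synthesis, 0.0789 to 0.747 for bile acid genes, 0.0103 to 0.987 for gluconeogenesis, 0.0181 to 0.647 for stress response genes, 1.8e-10 to 0.204 for interferon-stimulated genes, 0.0325 to 0.897 for matrix genes, and 0.247 to 0.879 for apoptosis and p53 targets. They ranged from 0.0181 to 0.987 for CAR/PXR targets, 0.00757 to 0.266 for male-biased genes, 0.0999 to 0.964 for female-biased genes, 0.301 to 0.943 for clock genes, 5.0e-09 to 0.646 for ribosomal proteins, 0.00563 to 0.82 for endothelial markers and 0.176 to 0.765 for stellate markers.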

Other observations

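The genes in this part were chosen after their values were seen, as were the tests of ribosomal protein genes, of HKO 1 against the Flox range and of both explanations for the Kupffer markers. The tests of gene length, of the chromosome 4 segment, of copies and of other splits were written before their results.

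Single livers differed widely in some genes of hepatic programs. The serum amyloid gene Saa1 stood at 476, 65.9 and 11.3 FPKM in Flox 1 to 3 and at 238, 53.7 and 99.6 in HKO 1 to 3, a range of 42.2-fold among Flox livers. The fatty acid hydroxylase gene Cyp4a14 stood at 41.5, 36.3 and 118 FPKM in Flox and at 192, 37.2 and 3.34 in HKO, 57.6-fold between the highest and lowest HKO liver, and Cyp4a10 spanned 24.1-fold there. HKO 1 held the highest levels of the stress genes Mt1 (47.8 FPKM, with the other 5 livers at 3.94 to 14.4) and Lcn2 (30.9 FPKM, the others at 2.20 to 10.1). Lipogenic enzymes followed another division, with Fasn at 163 and 147 FPKM in Flox 3 and HKO 3 and 18.3 to 45.8 in the other 4 livers, and Scd1 at 1480 and 1590 against 153 to 445. The urinary protein gene Mup20, a pheromone under growth hormone control, stood at 3030, 3950 and 1240 FPKM in Flox and 509, 1280 and 1460 in HKO. Igfbp1, which insulin represses, stood at 33.0, 117 and 49.1 and at 13.1, 62.0 and 97.2 FPKM, and the immediate-early gene Egr1 was highest in HKO 2 (44.6 FPKM, the others at 3.56 to 14.2).

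Among the interferon targets, Ifit1 stood at 5.12, 5.55 and 124 FPKM in Flox and 6.56, 4.20 and 4.24 in HKO, so that 1 control liver carried this program. Mesothelial markers had a score of 1 in HKO 3 and of -0.48 to 0.02 in the other 5 livers. HKO 2 and HKO 3 stood apart in a small set of transcripts. Setting these 2 libraries against the other 4 gave 9 genes past the adjusted threshold in limma, where the other 14 of the 15 splits of 2 against 4 gave 0 to 2. At an unadjusted p under 0.05 in limma it gave 1268 genes. Setting Flox 1 and Flox 2 apart gave 2096, the most of the 15 splits. The 9 genes included mt-Tp, Rps12-ps3 (17.5 and 17.7 FPKM, the other 4 at 54.5 to 85.6) and Rpl38-ps2 (50.6 and 51.2 FPKM, the others at 113 to 131), which were lower. Gm13342 was higher, at 2.89 and 2.61 FPKM against 0.272 to 0.651, from 10 reads in each of these 2 libraries. Rpl21 held 1155 reads in HKO 1 and 172 to 297 in the other 5 libraries.

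Nuclear-encoded OXPHOS genes were lower in HKO by a mean log2 fold change of -0.24. The mean was -0.18 once a trend of fold change on gene length was removed, so that trend took up a part of the difference. Before removal the mean lay below the 2.5th percentile (-0.20) of 10000 random lists matched on length and expression. Of these lists 0.19% were as low. These random lists had a mean of -0.14, so much of the difference was shared with other genes of that length and expression. Drawn from unrelated genes, they do not carry the correlation of 0.53 between members of the list. Their percentile therefore does not decide whether length was the whole cause. Whether all short abundant transcripts shifted cannot be told apart from a change of this pathway, because ribosomal protein genes had a mean of 0.06 (SE 0.025) over all libraries and -0.10 without HKO 1. A library difference shared by HKO 2 and HKO 3 stays open as a candidate explanation. The score of HKO 1 (0.06) lay within the Flox range of -0.11 to 0.27. The lowest Flox score was that of Flox 3, which lay below HKO 1. The scores thus divided Flox 1, Flox 2 and HKO 1 from Flox 3, HKO 2 and HKO 3, as did the first principal component. This division crosses genotype, and its part in the pattern was not tested. An effect of G3bp1 loss on respiratory genes may also account for part of the pattern. These data do not separate it from the differences between libraries.

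Kupffer cell markers were higher in HKO. A smaller share of hepatocytes would raise the markers of other cell types alike. Kupffer markers exceeded 30 endothelial and stellate markers by 0.50 (SE 0.09 over markers) in mean log2 fold change. Markers correlate within the same 6 livers (0.51 for Kupffer, 0.64 for endothelial). The SE thus does not measure the spread between livers. Markers of other macrophages, B cells, and T and NK cells had means of 0.31, 0.25 and 0.22. Those of endothelial, stellate and cholangiocyte cells had means of 0.10, -0.02 and 0.03. Whether a smaller hepatocyte share took part is not decided by these values. More Kupffer cells in HKO livers and higher expression per cell may each explain the pattern as a hypothesis. These cannot be told apart, because the 12 markers that hepatocytes lack belong to the list that showed the pattern, so that their direction was no separate test. The most abundant of these, C1qa and Cd5l, stood at 40.5 ± 9.61 and 39 ± 16 FPKM in Flox and 50.6 ± 17.8 and 63.9 ± 21.1 in HKO. Flox 3 (score 0.14) lay above HKO 2 (-0.02).

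Gm12411 and Mup13, both members of multigene families on chromosome 4, were lower in every HKO library than in every Flox library. A chromosome 4 segment of another strain, carried along with an allele, would make neighbours differ too, and between 40 and 70 Mb 6.5% of 168 genes (95% upper limit 11.4%) had an unadjusted p under 0.05 against 7.6% of other genes (Fisher's exact test, one-sided p = 0.743). Reads moving between near-identical copies cannot be told apart from a change in transcription, because the summed scaled reads of the other Gm12411 copies changed by 116 (SE 354) where Gm12411 lost 123, and those of the other Mup13 copies by -14844 (SE 34649) where Mup13 lost 596. A variant inside the genes themselves was not tested. The targeted gene G3bp1 lies on chromosome 11, as do Afmid, Trp53 and Krt23 among the genes named as lower. A segment around G3bp1 was not tested.

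The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes past the adjusted threshold 3 splits gave a count as large as the real 1, the highest other being 10 with Flox 1, Flox 2 and HKO 1 on the same side. For genes at an unadjusted p under 0.05, 2 splits gave as many as the real 904. The highest other was 2303, for that same division. That division crosses genotype, and what it reflects was not tested. For lists past camera 3 splits gave as many as the real 20, the highest other being 20. Every split other than the real one gave 10 to 20 lists. Camera with the preset correlation thus called many lists also between groups that mix genotypes.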
